A study of Homo sapiens with 4 samples.

How the data were processed

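Total RNA of 4 cultures was hybridized to Illumina bead arrays, 1 array per group: LM and HM20 cells, each untreated or with Wnt3a for 24 hours. RNA was extracted with TRIzol, cleaned on RNeasy columns with DNase I and turned into biotinylated cRNA with the Illumina TotalPrep kit, per the labels. The scanner software, the normalization tool and the genome build are not given in the sources used here. The authors deposited a table of non-normalized signals, which holds 1 linear intensity per probe and array without background subtraction, and beside each intensity a detection p-value, per the file headers. These p-values moved in steps of 1/770. The authors also deposited an annotated table of normalized intensity values. From the values, these were quantile normalized without background subtraction: 100 percent lay within 1 percent of a quantile normalization of the non-normalized signals, and 99.6 percent of sorted ranks were equal within 0.1 percent on all arrays. The series value table equalled the annotated table, within rounding, in 188888 of 188888 cells. Columns were matched to samples by name, with the suffix W read as the Wnt3a of the sample titles, and 0 columns of sample values were left unused.

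The non-normalized intensity values the authors deposited were processed with the neqc function of limma 3.58.1 in R 4.3.3. It subtracts a background fitted from the detection p-values, adds an offset of 16, quantile normalizes the arrays and takes log2. Of the probes, 33.0, 33.0, 29.8 and 30.9 percent had a detection p under 0.01 in LM, LM with Wnt3a, HM20 and HM20 with Wnt3a. The background signal was 108, 107, 135 and 129 and the median signal 1.12, 1.14, 1.13 and 1.14 times the background in the same order, so most probes lay near the background and low levels were measured poorly. Per gene, the brightest probe among those detected on at least 1 array was used, which gave 14649 genes from 18719 probes. An undetected value was set to the array's floor, its lowest detected value (log2 5.87, 5.87, 6.19 and 6.07), and no difference was taken when both arrays of a pair were undetected. Gene names came from the annotated table, and were updated for 8788 probes through the gene number with the RefSeq table for GRCh38.p14, from which no coordinates were used. For 8287 probes the file's symbol was kept, 3270 had none, and 54 symbols had been turned into dates. Y-linked genes, XIST and the X-linked VCX genes, whose probes resemble Y-linked copies, were left out of the tables of genes.

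Choices were made before the data were examined unless named otherwise. The comparisons were HM20 over LM untreated and Wnt3a-treated, and Wnt3a over untreated in LM and HM20. A gene was counted when at least 2-fold different, with no test, since each group had 1 array. The pairs of each contrast were compared by correlation across genes and by genes at least 2-fold the same way in both. An additive limma model with a cell line and a Wnt3a term was fitted to the 4 arrays with the eBayes function. The model used normalized values without the floor, so undetected signals entered as measured. It left 1 residual degree of freedom, with 6.46 prior degrees of freedom and a prior SD of 0.297 log2. P-values were adjusted by Benjamini-Hochberg over all genes and, for lists, also over the list alone, with a threshold of 0.05. For 25 gene lists, the median difference was placed among 10000 random lists matched in 20 bins of signal. The lists were epithelial, mesenchymal, EMT factor, canonical Wnt target, Wnt component, stem cell, protease, integrin, proliferation, interferon, NF-kB, TGF-beta and BMP, Notch, NRF2, lung, hypoxia, ER stress, cholesterol, p53, immediate early, YAP/TAZ, leukocyte, endothelial, fibroblast and housekeeping genes.

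Genes were named by a fixed rule. It took the 12 highest and lowest for HM20 over LM by the mean of both pairs, among genes at least 2-fold the same way in both. It took the 8 highest and lowest for Wnt3a in each line, up to 10 genes at least 2-fold the same way in both lines, and the 6 largest and smallest differences of response. It added up to 4 members of each list for HM20 over LM and up to 3 for Wnt3a, and a panel of 20 genes. Genes with provisional names were counted but not named by the first parts of the rule, and were named only where a count of both lines was given in full. Other members of a list are named only as examples of its count, and genes after the cancer-testis families were chosen after the values were seen.

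The steps were tested on simulated data. In the additive model, limma called 34 percent of 50 genes set at 1 log2 and 100 percent of those set at 2, 3 and 5, with 5 of 14449 unchanged genes called. By size alone in the untreated comparison, 76 percent of genes set higher by 1.5 log2 were counted and 100 percent at 2, 3 and 5. Of genes set lower, 47.6, 77.3, 60.9 and 61.1 percent were counted at 1.5, 2, 3 and 5, since the floor shortens differences of weak genes, and 291 of 12558 unchanged genes were counted. Alternatives were median scaling in place of quantile normalization, no background correction, the authors' normalized values, an offset of 50, a detection p under 0.05, no detection filter and no floor, no floor alone, the mean of a gene's probes, a 1.5-fold threshold and an intensity trend in eBayes. Recentring of the median-scaled differences on the median difference was added after the data were seen. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 made the tables and figures.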

Results

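Gene expression was measured on 4 Illumina bead arrays of a human lung cancer cell model. A549 is a lung adenocarcinoma cell line. Per the labels, LM cells were A549 cells that had grown as floating spheres and were then put back on adhesive plates. HM20 cells were LM cells passed 20 times, 1 passage after another, through membranes coated with Matrigel, a basement membrane gel that invasive cells can cross. Each of the 2 cell lines was profiled untreated and after 24 hours with Wnt3a, a secreted protein that activates beta-catenin signalling. The design therefore asks how the invasion-selected cells differ from LM cells, with and without Wnt3a, and what Wnt3a does in each. Each group had 1 array, so no difference below has a replicate check. The additive model named below uses the untreated and the Wnt3a-treated pair of the same 2 cell lines in place of replicates. Its p-values rest on how these pairs disagree and do not cover the spread between independent selections of the lines. Of the probes, 15601 (33.0 percent) were detected in untreated LM, 15595 in LM with Wnt3a, 14091 in untreated HM20 and 14587 in HM20 with Wnt3a. The signal at the 95th percentile of probes was 13.3, 14.7, 14.7 and 15.3 times the background in the same order. In all, 14649 genes were detected on at least 1 array. For a gene detected on 1 array of a pair, the fold is a bound set by the detection floor of the other array and is written "at least", and the order among such bounds has no meaning.

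HM20 cells differed from LM cells by lower levels of most epithelial transcripts and higher levels of mesenchymal ones. CDH1, which encodes the adherens junction protein E-cadherin, was at least 116-fold lower in HM20 than in LM among the untreated arrays and at least 117-fold lower among the Wnt3a-treated arrays. EPCAM, an epithelial cell adhesion molecule, was at least 143-fold lower in both pairs, and the tight junction gene CLDN7 was at least 65.8-fold and 67.5-fold lower. VIM, the mesenchymal intermediate filament vimentin, was 116-fold higher untreated and 156-fold higher with Wnt3a. PLAU, the urokinase protease that activates plasminogen, was 71.4-fold and 103-fold higher, and the Wnt antagonist SFRP1 was at least 55.6-fold and 73.3-fold higher.

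Of the 47 epithelial junction and keratin genes compared, 39 were at least 2-fold lower in untreated HM20 and 1, KRT15, was higher, while with Wnt3a 40 were lower and 0 higher. The median log2 difference of this list was -2.87 untreated and -3.04 with Wnt3a, and both lay at percentile 0 of 10000 random lists matched on signal. The mesenchymal and matrix list had only 24 of 46 members detected on at least 1 array, against 48 of 51 for the epithelial list. Of the 21 mesenchymal and matrix genes compared in the untreated pair, 13 were at least 2-fold higher and 3 lower (GAS6, TPM1 and TGFBI), with a median of 1.72 at percentile 100. In the Wnt3a-treated pair 13 of 24 were higher and 2 lower, with a median of 1.90. MTAP, a gene of methionine salvage that A549 is known to lack, was detected on both LM arrays and on neither HM20 array (log2 difference at or below -2.76 untreated and -2.41 with Wnt3a), and 9 of 15 intestinal epithelium genes were at least 2-fold lower in HM20 in both pairs. Both were looked at after the values were seen. Among the mesenchymal genes the actin-binding tropomyosin TPM2 was 110-fold and 57.5-fold higher, the collagen VI gene COL6A1 at least 50.6-fold and 46.0-fold higher, and the calcium-binding protein gene S100A4 13.1-fold and 29.2-fold higher. EMT transcription factors, the regulators of the epithelial to mesenchymal transition, went both ways. PRRX2 was at least 15.9-fold and 30.7-fold higher, SNAI2 at least 3.88-fold and 10.9-fold higher and TWIST2 at least 3.77-fold and 2.09-fold higher, whereas SOX4 was 16.3-fold lower untreated and FOXQ1 11.3-fold and 13.8-fold lower. FN1, ZEB1 and TWIST1 were detected on none of the 4 arrays, and CDH2 was detected only in LM with Wnt3a.

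Canonical Wnt and beta-catenin target genes were more often lower than higher in HM20. Of 37 compared, 15 were at least 2-fold lower and 9 higher untreated, with a median of -0.59 at percentile 0.09, and 17 were lower and 9 higher with Wnt3a, with a median of -0.67. Of the 38 detected members, 16 were also in another list, as were 11 of 28 stem cell markers and 8 of 29 TGF-beta and BMP genes. The lists are therefore not independent of each other. AXIN2, a feedback inhibitor induced by beta-catenin, was at least 97.6-fold and 58.9-fold lower, BMP4 was 140-fold and at least 189-fold lower, and the intestinal transcription factor CDX2 was at least 47.1-fold and 79.6-fold lower. PLAUR, the urokinase receptor, was 10.5-fold and 13.1-fold higher. Among 39 Wnt pathway components compared untreated, 7 were lower and 6 higher, and with Wnt3a 11 of 38 were lower and 5 higher, with a median of -0.31 at percentile 1.99 that became 0.04 without the detection filter and floor. CTNNB1, which encodes beta-catenin, was 2.98-fold and 2.66-fold lower, LEF1, a transcription factor partner of beta-catenin, at least 6.76-fold and 12.4-fold lower, and DKK3 at least 24.1-fold and 27.2-fold higher. Cyclin D1, CCND1, was 2.21-fold and 2.40-fold lower. NKD1, DKK1 and LGR5 were not detected on any array.

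Of the 27 cancer stem cell markers compared, 8 were higher and 7 lower untreated, and 8 were higher and 10 lower with Wnt3a. PROM1, the gene of CD133, was at least 8.72-fold and 23.7-fold higher and ITGB3 at least 11.2-fold and 11.4-fold higher, while CD24 was at least 53.7-fold lower untreated and 38.4-fold lower with Wnt3a, and ALDH3A1 was at least 20.5-fold and 33.3-fold lower. CD44 was 2.37-fold higher untreated and 1.08-fold higher with Wnt3a, and ALDH1A1, detected only in LM, lay within 1.12-fold of the HM20 floor. ABCG2 was detected only in HM20 with Wnt3a. Of the matrix proteases and inhibitors, 10 of 26 were higher and 3 lower untreated, and 11 of 27 were higher and 7 lower with Wnt3a; the metalloprotease ADAM19 was at least 23.1-fold and 33.0-fold higher. Of the integrins, 5 of 14 were higher and 3 lower untreated and 3 of 13 higher and 3 lower with Wnt3a, with ITGA2 4.82-fold and 8.11-fold higher and ITGB5 5.91-fold and 4.21-fold lower. Among Notch pathway genes 7 of 19 were higher and 2 lower untreated, with the Notch target HEY1 at least 66.9-fold and 74.6-fold higher and HES1, another target, 5.56-fold and 7.82-fold lower.

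Hypoxia and glycolysis genes were higher in HM20 in both pairs, 16 of 31 untreated against 3 lower (median 1.02) and 20 of 33 with Wnt3a against 2 lower (median 1.54), each median at percentile 100. BNIP3, a mitophagy receptor, was 81.1-fold and at least 85.2-fold higher, the aldolase ALDOC 26.1-fold and 38.4-fold higher and the enolase ENO2 18.0-fold and 15.1-fold higher. Proliferation genes were higher in HM20, 11 of 40 untreated and 16 of 38 with Wnt3a with 0 lower in either pair, and their medians of 0.58 and 0.89 were at percentile 100. The mitotic kinase AURKB was 3.36-fold and 5.32-fold higher. ER stress and amino acid response genes were lower, 20 of 30 untreated and 23 of 30 with Wnt3a, with 2 higher in each pair and medians of -1.66 and -1.67 at percentile 0. The stress transcription factor DDIT3 was 7.94-fold and 26.2-fold lower, ATF3 at least 16.8-fold and 17.7-fold lower and the serine synthesis enzyme PSAT1 5.66-fold and 10.8-fold lower. TGF-beta and BMP response genes were lower in 11 of 27 and higher in 5 untreated (median -0.70), with the differentiation inhibitor ID2 at least 64.5-fold and 66.7-fold lower and BAMBI at least 45.2-fold and 58.7-fold lower.

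The remaining lists are given as members higher and lower in HM20, untreated and then with Wnt3a. Interferon-stimulated genes had 9 and 7 of 34, then 9 and 6 of 36, with untreated HLA-B 8.73-fold higher. Inflammatory cytokine and NF-kB genes had 3 and 2 of 16, then 3 and 5 of 21, with untreated the chemokine CXCL8 25.2-fold higher and LCN2 at least 28.4-fold lower. NRF2 target and xenobiotic genes had 7 and 10 of 34, then 7 and 14 of 36, where the median was -0.52 at percentile 0.23, with untreated the aldose reductase AKR1B1 12.5-fold higher. Cholesterol and fatty acid synthesis genes had 2 and 5 of 31 untreated (median -0.24), then 9 and 2 of 31 with Wnt3a (median 0.63 at percentile 99.8), with untreated the fatty acid elongase ELOVL5 at least 19.9-fold higher. Target genes of p53 had 1 and 5 of 20, then 0 and 5 of 22, with untreated GDF15 at least 183-fold lower and BAX higher. Immediate early genes had 6 and 7 of 27, then 7 and 10 of 26, with untreated DUSP6, a phosphatase that acts on ERK, 11.3-fold lower. YAP/TAZ target genes had 3 and 7 of 21, then 4 and 6 of 22, with untreated CCN2 7.76-fold lower. Lung lineage genes had 2 and 3 of 12, then 2 and 3 of 8, with untreated CAV1 16.1-fold higher and FOXA1, a pioneer transcription factor of lung epithelium, at least 104-fold lower.

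Markers of leukocytes, of fibroblasts and pericytes and of endothelial cells were mostly undetected. Of 22 leukocyte markers 5 were detected, of which untreated 1 (CD68) was higher and 1 (CORO1A) lower in HM20. Of 21 fibroblast and pericyte markers 2 were detected, with FBLN1 at least 28.9-fold and 22.2-fold higher in HM20. Of 16 endothelial markers 5 were detected, with a median of 1.61 untreated, and ESAM was at least 11.1-fold and 9.20-fold and PECAM1 at least 5.79-fold and 5.74-fold higher in HM20. Of 29 housekeeping genes, 4 were at least 2-fold higher and 2 lower untreated, and their median of -0.03 became 0.10 with arrays scaled to equal medians, where the median of all compared genes was 0.14. With Wnt3a 5 were higher and 0 lower, with a median of 0.28 at percentile 97.1.

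The 12 genes taken by the highest mean difference, most of them bounds, were all of the GAGE family, cancer-testis genes normally restricted to the germ line. GAGE12J, 1 of them, was at least 512-fold higher untreated and 496-fold higher with Wnt3a. GAGE copies are near-identical in sequence and a probe can bind several, so the 12 values are uncertain as single genes. Past the cancer-testis genes, a selection made after the values were seen, EMP3 was at least 151-fold and 140-fold higher, the neuronal ubiquitin hydrolase UCHL1 at least 101-fold and 120-fold higher and the galectin LGALS1 87.6-fold and 119-fold higher. The lowest genes besides those above were S100P, at least 268-fold and 251-fold lower, SPINT2, an inhibitor of epithelial serine proteases, at least 151-fold and 123-fold lower, the sodium channel subunit SCNN1A at least 95.2-fold and 82.5-fold lower, OLR1 at least 81.9-fold and 93.1-fold lower, the metallothionein MT1E 80.6-fold and at least 92.5-fold lower, and TNNC1 at least 106-fold and 48.7-fold lower.

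Across all genes compared, 1796 were at least 2-fold higher and 1737 lower in HM20 among 13613 in the untreated pair, and 2065 were higher and 2138 lower among 13658 in the Wnt3a-treated pair. Of the genes at least 2-fold different, 1279 and 1331 respectively had only a bound. The pairs share no array, and across the 12622 genes compared in both, the differences correlated at r = 0.897 (Pearson) and rho = 0.814 (Spearman), with genes not being independent replicates. In both pairs 1340 genes were at least 2-fold higher and 1332 lower, against 290 and 291 for independent lists, and 1 gene, TXNIP, was at least 2-fold different in opposite directions. An additive limma model over the 4 arrays, in which the disagreement of the pairs is the error, called 2389 genes higher and 2532 lower of 14649 at an adjusted p under 0.05. VIM had an adjusted p of 7.30e-06, CDH1 4.00e-06, PLAU 1.04e-05, AXIN2 1.52e-05 and CTNNB1 0.00546 in this limma model, and each was on the same side in 2 of 2 pairs. It called 44 epithelial genes lower and 1 higher of 48 tested (44 and 2 adjusted over the list alone), and 13 mesenchymal genes higher and 6 lower of 24 (13 and 6 adjusted over the list alone). The model called 19 canonical Wnt targets lower and 8 higher of 38 and 22 hypoxia genes higher and 3 lower of 33, which became 19 and 8 and 23 and 3 when adjusted over the list alone. It called 23 ER stress genes lower and 2 higher of 30 and 15 proliferation genes higher and 0 lower of 40, which became 24 and 2 and 16 and 0 adjusted over the list alone. The model has 1 residual degree of freedom per gene and counts a true difference in Wnt3a response as error. It also used undetected signals without the floor, as for CDH1 and AXIN2 in HM20.

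**Figure D1:**
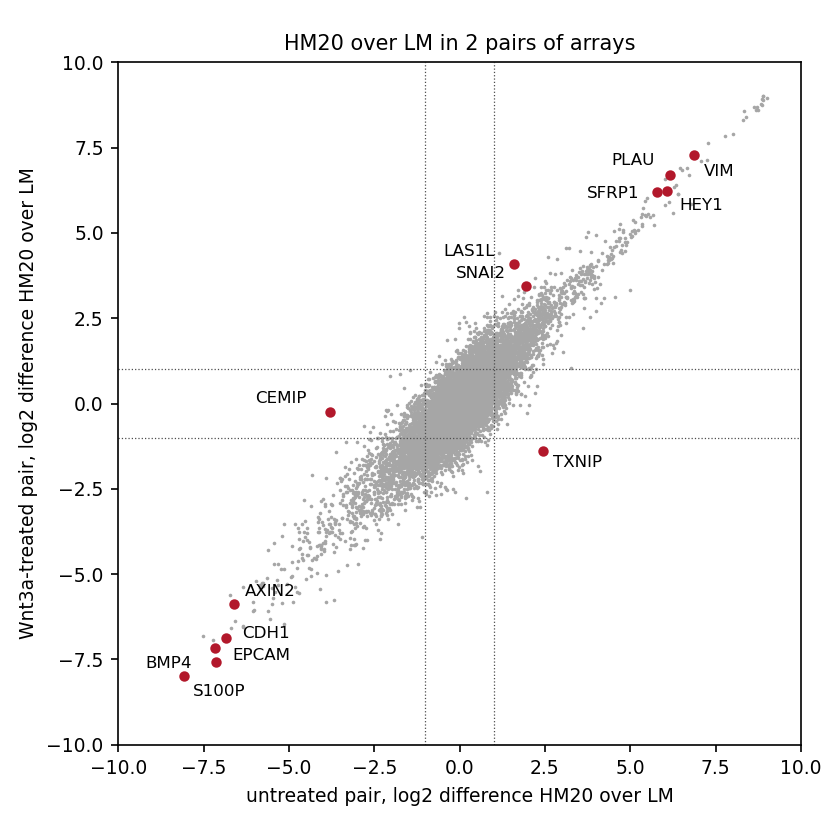
Log2 difference of HM20 over LM for each gene in the untreated pair (horizontal axis) and in the Wnt3a-treated pair (vertical axis), with dotted lines at 2-fold and named genes in red. The genes lie along the diagonal (r = 0.897 across 12622 genes, Y-linked genes not drawn), with TXNIP and CEMIP away from it.

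Wnt3a in LM cells went with lower transcripts of cholesterol and lipid synthesis and higher transcripts of histones and of xenobiotic metabolism. INSIG1, the sterol sensor that retains SREBP in the endoplasmic reticulum, was 7.52-fold lower with Wnt3a than without, and ACAT2, which makes the first intermediate of the sterol pathway, was 6.56-fold lower. MSMO1, a sterol oxidase, was 4.73-fold lower. The histone genes H2BC5 and H1-2 were 9.04-fold and 8.73-fold higher, and the aryl hydrocarbon receptor targets CYP1B1 and CYP1A1 were 4.48-fold and at least 8.80-fold higher. The aldo-keto reductases AKR1C2 and AKR1C4 were 7.16-fold and 6.72-fold higher.

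Of 29 cholesterol and fatty acid synthesis genes compared in LM, 19 were at least 2-fold lower with Wnt3a and 0 higher, with a median of -1.13 at percentile 0. Of 35 NRF2 target and xenobiotic genes, 9 were higher and 0 lower, among them NQO1 and TXNRD1, with a median of 0.37 at percentile 100. AKR1C and histone copies resemble each other in sequence, so single members are uncertain. Proliferation genes had a median of -0.44 at percentile 0, with 7 of 39 at least 2-fold lower and 0 higher, among them the replication factors CDC45 at 3.22-fold, GINS2 at 2.61-fold and MCM2 at 2.48-fold lower. Integrins had a median of -0.46, which became 0.02 without the detection filter and floor, with ITGA3 2.28-fold and ITGA9 2.12-fold lower and 0 of 11 higher. Of 36 canonical Wnt targets, 3 were higher (CLDN1 5.07-fold, CD44 2.42-fold and TCF7L2 2.37-fold) and 3 lower (VEGFA 4.82-fold, MYC 2.35-fold and ASCL2 2.11-fold). Their median was -0.25 at percentile 1.59, and became 0.01 with arrays scaled to equal medians, where the median of all compared genes was 0.20. AXIN2 was 1.80-fold lower and LEF1 1.70-fold higher. Of 38 Wnt pathway components, 4 were higher and 1, CTNNBIP1, lower, and CTNNB1 was 1.40-fold higher.

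Of 47 epithelial genes 5 were higher, among them CLDN1 and the desmosomal cadherin DSC2 at 3.72-fold, and 2 lower, among them PRSS8 at 3.29-fold. Of 16 mesenchymal genes 0 reached 2-fold, with a median of -0.38, and VIM was 1.40-fold lower. Hypoxia and glycolysis genes had 3 of 31 lower, VEGFA, SLC2A3 at 3.14-fold and PFKP at 2.35-fold, and a median of -0.21 at percentile 4.06, which became 0.02 under the same scaling, below the 0.20 of all compared genes. Of 34 interferon-stimulated genes 3 were higher, with SAMD9 at 4.07-fold, and 1, IRF1, was lower. Of 26 immediate early genes 4 were lower, among them ZFP36 at 2.63-fold and FOS at 2.38-fold. Of 27 TGF-beta and BMP response genes 3 were higher, among them ID3 at 3.88-fold and THBS1, and 1, PMEPA1, was lower. Of 29 housekeeping genes, GPI at 3.56-fold and TUBB at 2.60-fold were lower and 0 higher, with a median of -0.23 at percentile 2.03. The other leading genes of the comparison were LAS1L, a ribosome assembly factor, at 6.97-fold, REEP6 at 5.84-fold, PDE9A, a cyclic GMP phosphodiesterase, at 5.78-fold, LIPG, an endothelial lipase, at 4.99-fold and the DNA repair gene FANCL at 4.84-fold lower. The pseudogene KRT18P59, named as a copy of KRT18, was 4.92-fold lower. KRT18 itself was at least 2-fold lower too, so the 2 may not be separate signals.

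In all, 524 genes were at least 2-fold higher and 500 lower with Wnt3a among the 13327 compared in LM. Scaling the arrays to equal medians in place of quantile normalization put the median of the compared genes at 0.20 log2, against -0.01, and gave 1063 higher and 196 lower, so the balance of higher and lower genes was not settled. The same scaling put the median of the untreated HM20 over LM comparison at 0.14 log2, against 0.05. Of 134 genes with a second probe and a difference of at least 2-fold by the first, 116 had the second probe on the same side of 0 and 42 also at least 2-fold.

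Wnt3a in HM20 cells went with few differences of 2-fold, led by SCG2 on the higher side and DDIT3 on the lower. They numbered 85 of 12010 genes compared, and with 1 array per group single genes below may be noise. The simulation counted 291 of 12558 unchanged genes, but it was of the untreated HM20 over LM comparison. Its noise, taken from the disagreement of the pairs, had an SD of 0.320 log2 on each array. The SD of all differences with Wnt3a in HM20 was only 0.314 log2, so the simulation cannot say how many of the 85 are noise. SCG2, a secretogranin of secretory granules, was 9.52-fold higher, EVA1A, a regulator of autophagy, at least 4.15-fold, the methyltransferase NNMT at least 3.71-fold and the hyaluronan-degrading CEMIP 3.44-fold higher. The collagen gene COL5A1 was 3.33-fold, MLLT11 3.22-fold, the noncoding RNA MEG3 3.21-fold and the interstitial collagenase MMP1 3.11-fold higher. DDIT3 was 3.98-fold lower, the asparagine synthetase ASNS 2.85-fold lower and TXNIP, which binds and inhibits thioredoxin, 2.73-fold lower. WNT7A was at least 2.52-fold lower, METRN 2.44-fold and the small Cajal body RNAs SCARNA11 and SCARNA23 2.89-fold and 2.55-fold lower, and NAV2 was lower too.

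Of 24 ER stress and amino acid response genes compared in HM20, 3 were at least 2-fold lower with Wnt3a (DDIT3, ASNS and SLC7A5) and 0 higher, and the median of -0.52 lay at percentile 0. The proliferation and cholesterol lists had 0 members at 2-fold and medians of -0.18 and -0.21, at percentiles of 0.03 and 0. Mesenchymal genes had 2 of 20 higher (COL5A1 and COL6A3), EMT transcription factors had 1 of 9 higher, SNAI2 at 2.80-fold, and PROM1, at 2.72-fold higher, was the only 1 of 20 stem cell markers to reach 2-fold. The median of that list was -0.19 at percentile 1.28, and became 0.01 without the detection filter and floor. None of 22 canonical Wnt targets reached 2-fold in HM20, AXIN2 and LEF1 were not detected in this line with or without Wnt3a, MYC was 1.43-fold lower and CTNNB1 1.56-fold higher. In all, 51 genes were at least 2-fold higher and 34 lower among 12010, and of the 4 genes with a second probe and a 2-fold difference, 2 had it at least 2-fold too.

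The differences with Wnt3a had little in common between the lines. Across the 10688 genes compared in both lines they correlated at r = 0.148 and rho = 0.135, again over genes that are not independent replicates. At least 2-fold higher in both lines were 4 genes (1.25 for independent lists): H2BC5, 9.04-fold in LM and 2.05-fold in HM20, ID3, an inhibitor of differentiation, 3.88-fold and 2.57-fold, the tRNA-modifying enzyme LCMT2 2.08-fold and 2.10-fold, and the provisional gene LOC727877. Lower in both was 1 gene (0.851 for independent lists), the provisional LOC100132761. The additive limma model called 0 genes for Wnt3a over both lines, with 716 of 14649 at an unadjusted p under 0.05 and a smallest adjusted p of 0.840, and with arrays scaled to equal medians it called 28 higher and 9 lower. Adjusted over the list alone, ID3 was called higher among the TGF-beta and BMP response genes and CD14 among the leukocyte markers, and the other 23 lists had 0 calls.

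The difference between the responses, taken as the log2 Wnt3a difference in HM20 minus that in LM, was largest for CEMIP and TXNIP, which went opposite ways. CEMIP was 3.42-fold lower with Wnt3a in LM and 3.44-fold higher in HM20, and TXNIP was 5.20-fold higher in LM and 2.73-fold lower in HM20. REEP6, PDE9A, LAS1L and FANCL, which were lower with Wnt3a in LM and less than 2-fold different in HM20, had differences of 2.87, 2.60, 2.48 and 2.41. On the other side, AKR1C4, H2AC6, H1-2, H2AC19 and H2AC18 followed TXNIP with -3.40, -2.81 or below, -2.55, -2.38 and -2.32. The H2AC6 value is a bound, as this gene was undetected in HM20 with Wnt3a. Among the 10688 genes, this signed difference was at least 1 log2 above 0 for 526 and at least that far below 0 for 557, whichever line it came from. With arrays scaled to equal medians these counts were 263 and 946, so their balance was not settled. No residual degree of freedom is left to test this difference, so it is given by size alone.

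**Figure D2:**
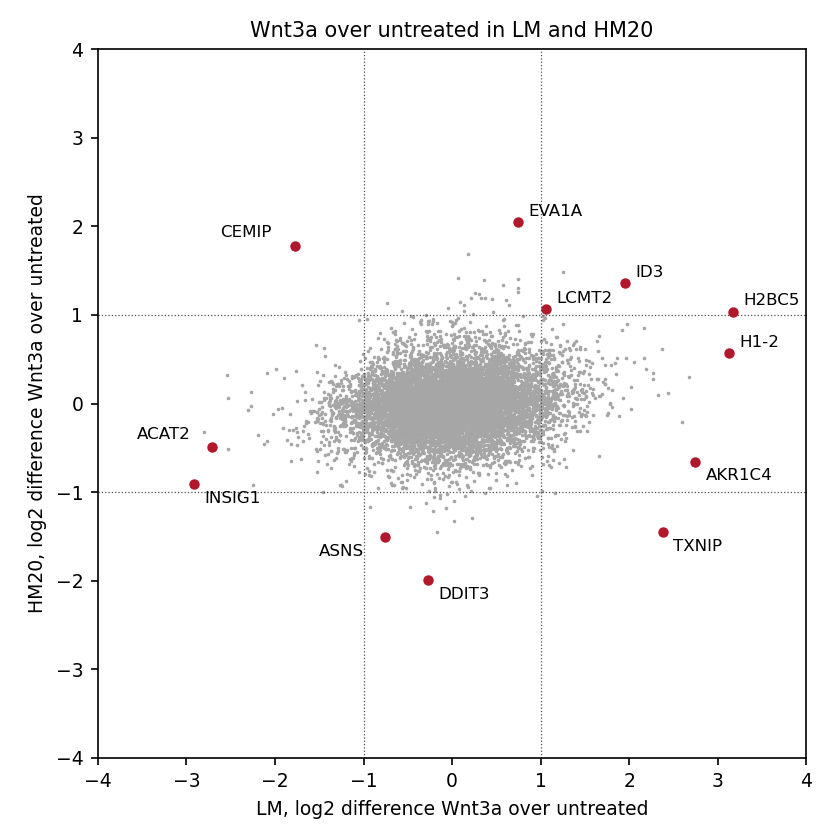
Log2 difference of Wnt3a over untreated for each gene in LM (horizontal axis) and HM20 (vertical axis), with dotted lines at 2-fold and named genes in red. The spread is wider in LM than in HM20 (SD 0.56 and 0.31 log2), and CEMIP and TXNIP lie in opposite corners.

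**Figure D3:**
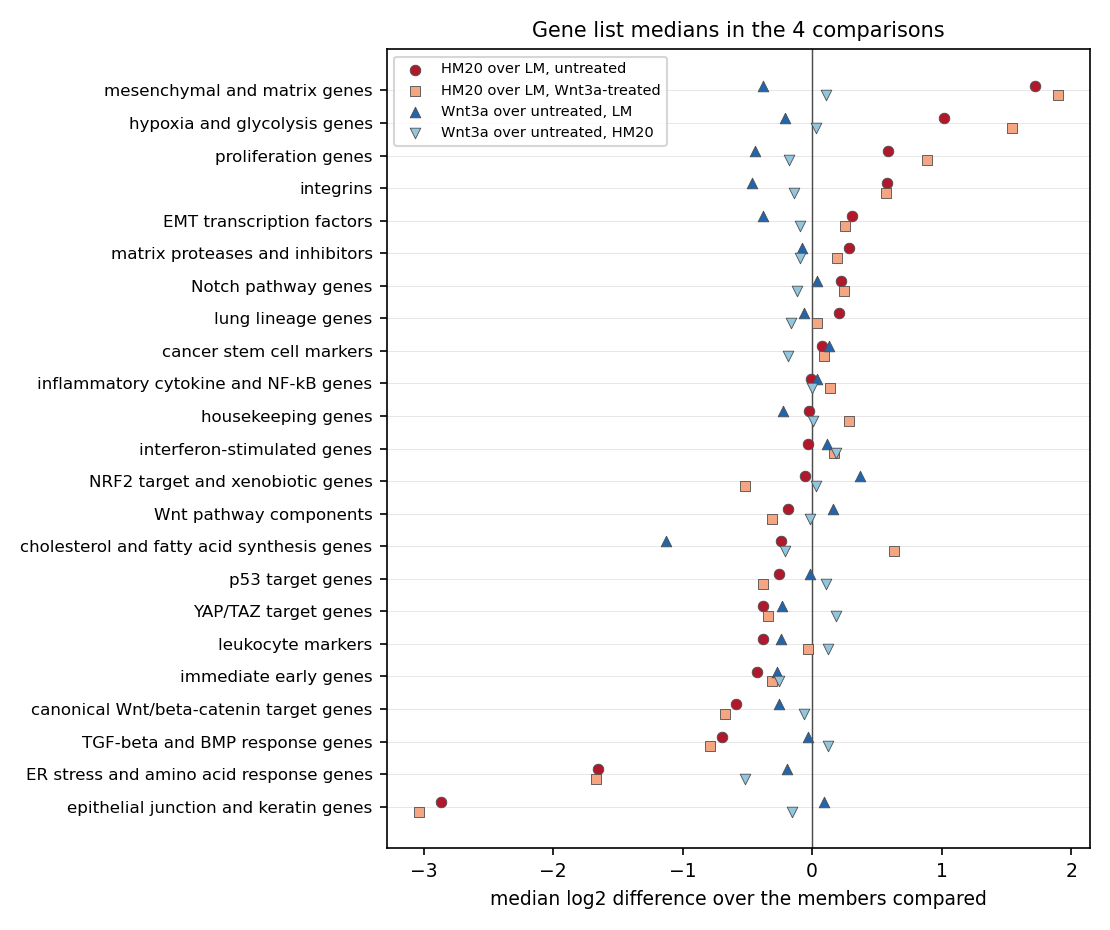
Median log2 difference of the gene lists that had at least 3 members compared in all 4 comparisons (symbols), ordered by the untreated HM20 over LM difference. The epithelial list is lowest at -2.87 and the mesenchymal list highest at 1.72. The median of canonical Wnt targets with Wnt3a in LM (-0.25) became 0.01 with arrays scaled to equal medians, where that of all compared genes was 0.20.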

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

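All explanations weighed here, with their tests and thresholds, were chosen only after the results were seen. The Wnt3a response of HM20 minus that of LM was flagged for 3 genes at least 2-fold different in opposite directions in the lines. It was 3.55 log2 for CEMIP, -2.16 for SLC35F6 and -3.83 for TXNIP. These differences were not tested, since no residual degree of freedom was left. SLC35F6 only just reached 2-fold in HM20, at -1.01 log2. Of the 10688 genes compared in both lines, 444 were at least 2-fold higher and 433 lower in LM, and 30 and 21 in HM20. A few opposite genes would therefore also come from independent lists.

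For the broad difference between LM and HM20, the first pattern weighed, normalization of the arrays was set aside as the cause, because at least 1556 genes stayed at least 2-fold different the same way in both pairs under the main and 8 alternative settings in which both pairs were counted. MTAP, a gene of methionine salvage that A549 is known to lack (background knowledge, not from these data), lay 2.613 log2 above the floor on the lower of the LM arrays and was undetected on both HM20 arrays. By the threshold set, this leaves open that the LM cultures may hold cells other than A549, but MTAP was read by 1 probe, which could also bind another transcript. Intestinal epithelium genes such as CDH17 and the HOX gene HOXA9 were high in LM and undetected in HM20 too. The other way round, NDN and SNURF of the imprinted SNRPN region were detected only in HM20, while MAGEL2 was detected in both lines. The series has no array of other A549 cells to compare these genes with. Neither line was therefore checked against A549, and whether HM20 holds only A549 cells was not tested either. Selection through Matrigel could be neither supported nor excluded. Of the 2672 genes different in both pairs, 57 (2.1332 percent) were in the epithelial, mesenchymal or EMT factor lists. These lists had only 48, 24 and 11 detected members, so the share had to be small whatever the cause and decides nothing. Selection can also move genes outside them.

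The Wnt3a difference in LM was the second. Noise of single probes was set aside as its main cause, because 86.5672 percent of the 134 genes at least 2-fold different by the brightest probe had their second probe on the same side of 0, though 42 of them reached 2-fold by it. Slower growth of the treated culture may account for part of it, as the median of the proliferation genes was -0.4398 log2, but the housekeeping genes had a median of -0.23 too, and 1 culture per condition cannot separate growth from treatment. A rise of the direct feedback targets of beta-catenin as a set was set aside. Their median was -0.6876 log2, with 5 of 8 lower by more than the SD of a pair's difference. In untreated LM their log2 signals ran from undetected for APCDD1 to 12.8 for AXIN2, so some were high before Wnt3a. The lack of a further rise therefore cannot exclude that Wnt3a activated the pathway. Under median scaling the median of these targets was -0.44, close to that SD of 0.407. LEF1 and SP5 were higher by 0.76 and 0.51, so single targets are left open.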

How the results depend on the processing

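The recentred scaling was chosen only after the results were seen, and all other alternatives before. Of 380 named gene differences of at least 2-fold, 380 kept their direction under each of the 8 alternatives run on gene values except the mean of probes, where 379 did and NRARP with Wnt3a in LM turned from -1.03 to 0.26. Still at least 2-fold were 363 with median scaling, 322 without background correction, 325 with the authors' values, 354 with an offset of 50, 363 with the mean of probes and 380 with the other detection and floor settings. Those detection and floor settings only lower or remove the floor and made 0 of 674 named values smaller, so by construction their 380 is no check. The counts of HM20 over LM in the additive limma model lay between 2389 and 2795 higher and 2532 and 2908 lower, and the intensity trend and the mean of probes moved no count by over 1.5 times. Signals with a median of 1.12 to 1.14 times the background limit what can be said of weakly expressed genes, whose folds depend on the floor and the background step. No paired analysis was possible because each group has only replicate number 1, and the additive limma model used line and treatment alone. The cause was not tested for any of the moves below, except where the construction of the alternative is named.

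Counts follow as higher and lower, in the order untreated HM20 over LM, Wnt3a-treated HM20 over LM, Wnt3a in LM and Wnt3a in HM20. A 1.5-fold threshold, which counts more genes by construction, gave 3205 and 3030, 3520 and 3499, 1759 and 1794, and 390 and 397. Without background correction, which by construction leaves background in both values of a ratio, they were 988 and 1045, 1222 and 1266, 199 and 174, and 13 and 5. The authors' values, also with background, gave 1057 and 1091, 1301 and 1333, 209 and 193, and 13 and 6. Without background correction and with the authors' values, respectively, genes different in both pairs of HM20 over LM numbered 779 and 838 higher and 777 and 819 lower. In the same order, the log2 Wnt3a difference in HM20 minus that in LM was at least 1 for 157 and 174 genes and -1 or below for 184 and 202. Under each of these settings 1 gene was higher and 0 lower with Wnt3a in both lines.

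Median scaling gave 1063 and 196 with Wnt3a in LM and 79 and 22 in HM20, 10 genes higher and 0 lower in both lines, and a difference of HM20 minus LM of at least 1 for 263 and -1 or below for 946 genes. Under it the limma model called 28 genes higher and 9 lower with Wnt3a, against 0. Recentred, the LM counts were 600 and 394, and all 8 counts stayed within 1.5 times of the main ones. An offset of 50, which draws log2 differences toward 0 by construction, gave 346 and 319 with Wnt3a in LM, 25 and 12 in HM20, 2 higher and 0 lower in both lines, and 352 genes with a difference of HM20 minus LM of -1 or below. A detection p under 0.05 gave 99 and 65 in HM20 and 3 genes lower in both lines.

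Without a detection filter and floor, 769 genes were lower with Wnt3a in LM, and 192 were higher and 171 lower in HM20, with 12 higher and 9 lower in both lines. There the difference of HM20 minus LM was at least 1 for 1304 and -1 or below for 1267 genes, and the Spearman rho of the cell line pairs was 0.531. Without the floor alone, 154 were higher and 115 lower with Wnt3a in HM20, and 11 higher and 8 lower in both lines.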

Other observations

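The gene families here, and the test at the end, were chosen only after the results were seen, and metallothionein, small nucleolar RNA, UGT, keratin and other imprinted genes were looked at too. Cancer-testis genes, normally restricted to germ cells, were higher in HM20 than in LM across several families. Of 8 detected cancer-testis genes outside the families of near-identical copies, 6 were at least 2-fold higher in both pairs, with medians of 4.38 log2 untreated and 4.26 with Wnt3a (2.89 and 2.78 without background correction). Gene values here are log2 differences in the untreated pair, and bounds where a gene was undetected in 1 of the lines. Among the 6 were MAGEA10 (at least 5.45), MAGEA4 (at least 5.35) and PRAME, a repressor of retinoic acid signalling (at least 3.86). Of 37 in families of near-identical copies such as GAGE, XAGE and MAGEA3 with MAGEA6, 35 were higher in both pairs, with values uncertain as single genes. Imprinted genes of the SNRPN region were higher, with NDN, a growth suppressor of neurons, at 5.30 or more, SNURF at 5.06 or more and the splicing protein gene SNRPN at 4.26, while MAGEL2 was at -0.38.

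HOX genes, which encode positional identity, were lower in HM20 in part of the HOXA and HOXB clusters and higher in part of HOXC, with no test between clusters. Of 8 detected HOXA genes 4 were lower in HM20 in both pairs, with HOXA9 at -5.42 or below, and of 9 HOXB genes 5 were lower and 1, HOXB2, higher. Of 4 HOXC genes 2 were higher, HOXC8 at 3.40 or more and HOXC13 at 1.47 or more. Without background correction 1 of the 4 was at least 2-fold higher in the untreated pair. Of 15 detected intestinal epithelium genes 9 were lower in both pairs, among them the cadherin CDH17 at -5.19 or below, the tetraspanin TSPAN8 at -5.40, the secretory protein AGR2 at -5.31 and the mucosal trefoil peptide TFF3 at -4.92 or below. With Wnt3a in LM, 13 of 27 replication-dependent histone genes were at least 2-fold higher and 0 lower, with a median of 0.73, against 0.24 in HM20. These medians were 0.40 and 0.11 without background correction and 0.42 and 0.12 with the authors' values, where 10 were higher in LM. Histone copies resemble each other, so single members are uncertain.

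Cross-hybridization between near-identical copies was weighed for the cancer-testis pattern. It may raise single members. By the threshold used, the 6 genes outside those families that were higher in both pairs would set it aside as the whole cause. The limits that follow keep this test from deciding the question. MAGEA3, MAGEA6, MAGEA9B, MAGEA12 and the CTAG genes were counted inside them, but MAGEA1, MAGEA4 and MAGEA10, also MAGEA genes, were among the 6. All 6 were detected only in HM20, so none could have been lower there. Probe sequences were not available to check the 6, so cross-hybridization is not excluded for them.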
